A study of Danio rerio with 2 samples.

How the data were processed

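Zebrafish larvae homozygous for lri25 and wild-type siblings from the same clutches were sampled at 5 days post fertilisation (dpf). Each genotype was represented by 1 pooled library made from 20 whole larvae of the AB/TL strain, so 2 libraries were compared with 1 library per group. Total RNA was extracted with the Qiagen RNeasy Mini kit and sequenced after standard Illumina library preparation, per the labels' protocols. The submitters' processing notes list the Zv9 zebrafish genome build, CASAVA and Bowtie, without versions, and the order and settings of these steps are not given in the sources used here.

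The values analysed were FPKM, fragments counted on a gene scaled to its transcript length and to the size of the library, in 1 deposited table with a column for the wild-type siblings and a column for the mutant, per the file headers. The same table holds the authors' own p-value and q-value for each gene, which compare these 2 libraries and not the genotypes. The program that computed the FPKM and the q-values is not given in the sources used here. The column names carry short codes for the wild type and the mutant, and they were matched to the labels' titles. Of the 33733 genes in the table, 10305 were listed at 0 in both libraries, 1449 at 0 in the wild type only and 976 at 0 in the mutant only. An exact 0 in a table of this kind can be a failed estimate, so such genes are described as listed at 0 and are given no fold.

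Several features of the table affected how it was read. Its first identifier column had been sorted apart from the rest. Of the identifiers in that column, 21937 were found in a table of zebrafish gene symbols and 0 carried the symbol printed on their line, ignoring case. Of those in the second identifier column, 21934 were found and 14491 carried that symbol, so the second column was used. In the deposited fold column, 977 values were spreadsheet error text and 11 others differed from the FPKM ratio by more than 0.01 on the log2 scale, so every log2 difference was recomputed. Spreadsheet software had turned 20 gene symbols into dates. Positions are those of the table, in build Zv9, written 1-based after 4 of 4 mitochondrial genes showed lengths that fit starts counted from 0. Overlapping genes share 1 locus in the table, which holds for 8287 genes, and their reads may have been divided between them. The libraries are not stated to keep the strand of the RNA. No Zv9 annotation was used here, so exons and untranslated regions are not described.

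The total number of fragments per library is not given in the sources used here, and counts were not recovered. Relative depth was read from genes with few fragments. Among 510 genes under 0.5 FPKM but above 0 in both libraries, 206 had a mutant to wild-type ratio between 0.7 and 0.83, with a median of 0.765. That would be 1 fragment in each library if the mutant library was 1.31 times deeper. A smaller group of 38 genes centred on a ratio of 0.381, as 1 fragment against 2 would give. For loci of 800 to 1500 bp, the lowest value above 0 was 0.32 FPKM in the wild type and 0.247 FPKM in the mutant, so genes near 1 FPKM rest on few fragments. No counting interval was computed, and no error is attached to any single value because each group had 1 library.

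The difference between the libraries was log2((mutant FPKM + 1)/(wild-type FPKM + 1)), which understates the difference of genes near 0. Genes with at least 1 FPKM in at least 1 library entered the comparison, which left 20256 genes. A gene was counted as higher or lower when this difference reached 1, a 2-fold difference. Folds printed beside single genes are plain ratios of the FPKM values. No test was run, since 1 library per group gives no spread between biological samples.

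Gene groups were described with 63 lists of cell type markers and pathways, fixed before the data were examined together with the comparison, the thresholds, the naming rule and most alternatives. Of 1878 list entries, 1767 were matched to the table, giving 1681 different genes, of which 80 were in more than 1 list. For each list, the median difference of its measured members was placed among the medians of 10000 random lists of the same size, drawn within 20 bins of mean level. A list beyond percentile 2.5 or 97.5 is called below or above the random range. By chance, 3.2 of the 63 lists would lie outside if genes varied independently. Genes of 1 cell type or pathway may move together between any 2 pools, so more lists could lie outside without an effect of the genotype. These percentiles describe the 2 libraries and are not p-values. Another 4 lists were written after the results had been seen, for inner retinal neurons, photoreceptor genes outside phototransduction, leukocyte identity genes and bipolar cell genes, the last a part of the first chosen after its values were seen.

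Genes are named by rule. The first part took the 12 genes with the highest and the 12 with the lowest difference among the 11172 genes with an assigned symbol and at least 5 FPKM in at least 1 library. The second took up to 4 members of each list outside the random range, those farthest in the direction of the list's median at 5 FPKM or more. The third took up to 2 members with the highest mean level of each list inside the range. This gave 197 genes, some of which are not reported here, and any other gene is said to be chosen after its values were seen.

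Alternatives were a pseudocount of 0.1 or 5, no floor or a floor of 5 FPKM, rescaling by a trimmed mean of differences (30% of differences and 5% of levels trimmed), centring on the median difference of genes at 10 FPKM or more in both libraries, a 3-fold threshold, list members at 5 FPKM or more only, random lists not matched on level, list means, and for the authors' calls a q of 0.01, a 2-fold minimum and a floor of 5 FPKM. Leaving out genes listed at 0 and leaving out genes at a shared locus were added after seeing the data. The procedure was tested on simulated data made from this comparison, in which 200 of 20256 genes, all at 5 FPKM or more, were set 4-fold apart at an assumed 2000000 fragments per library. It recovered 97.5% of them, placed 0.92% of the unchanged genes at that level past 2-fold, and put 6% of 200 random lists outside the range. The simulated mutant was rescaled by the trimmed mean, which the main comparison was not, and all simulated genes had 1 length. The 0.92% depends on the assumed fragments and does not measure the noise of these libraries. Random lists lie outside 5% of the time by construction. The simulated noise is counting noise only and does not contain differences between individual larvae. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.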

Results

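The deposited data hold transcript levels of whole zebrafish larvae at 5 dpf, in 1 library of 20 pooled lri25 homozygotes and 1 library of 20 pooled wild-type siblings. The series was designed to find which transcripts differ between lri25 mutants and their clutchmates. The labels used here do not name the gene that lri25 affects, so its transcript was not used to check the genotype labels. Both libraries had similar breadth, with 18975 genes at 1 FPKM or more in the wild type and 18791 in the mutant. The 10 most abundant genes held 13.8% of summed FPKM in the wild type and 15.2% in the mutant. With 1 library per genotype, no difference has a replicate check, and each value describes these pools.

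Transcripts of the visual photoreceptors were far lower in the mutant library. Rhodopsin (rho) stood at 1064 FPKM in the wild type and 27.5 FPKM in the mutant, and 23 of 24 cone and 21 of 22 rod phototransduction genes were at least 2-fold lower. Digestive enzymes of the exocrine pancreas were also lower, at least 2-fold in 14 of 18 genes. Higher in the mutant were genes of apoptosis and the DNA damage response, complement and acute phase proteins of the liver, and inflammatory signalling genes. Transcripts of fast muscle, mitochondria, ribosomes and cell division lay close together in the 2 libraries.

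Of 20256 genes compared, 1232 were at least 2-fold higher and 1442 at least 2-fold lower in the mutant library, around a median log2 difference of -0.01. Across the 17510 genes at 1 FPKM or more in both libraries, log2(FPKM + 1) correlated with a Pearson r of 0.942, a value across genes, which are not independent replicates. The share of genes at least 2-fold apart was 17.9% among 7498 genes whose higher value lay between 1 and 5 FPKM, and 9.38% among 3710 genes between 20 and 100 FPKM. In that second class 95% of genes lay between -1.51 and 1.31. The same range was -1.59 to 1.53 for the genes between 1 and 5 FPKM, and -2.17 to 1.53 for the 1009 genes above 100 FPKM. These counts depend on how low values are treated, and with a pseudocount of 5 they were 296 higher and 361 lower. Of the 197 genes chosen by rule for naming, 155 had a locus of their own in the table. Those at a shared locus, whose levels are less certain, included ompa, mipb, pla2g1b, gcga, vil1, cp, c3b, zgc:109934, tnfaip2b, ucp2, psme2, dnajb9b, sgk1 and hspa8, beside those marked at their values. Of the 63 gene lists, 17 lay above the range of random lists, 14 below it and 32 inside.

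**Figure D1:**
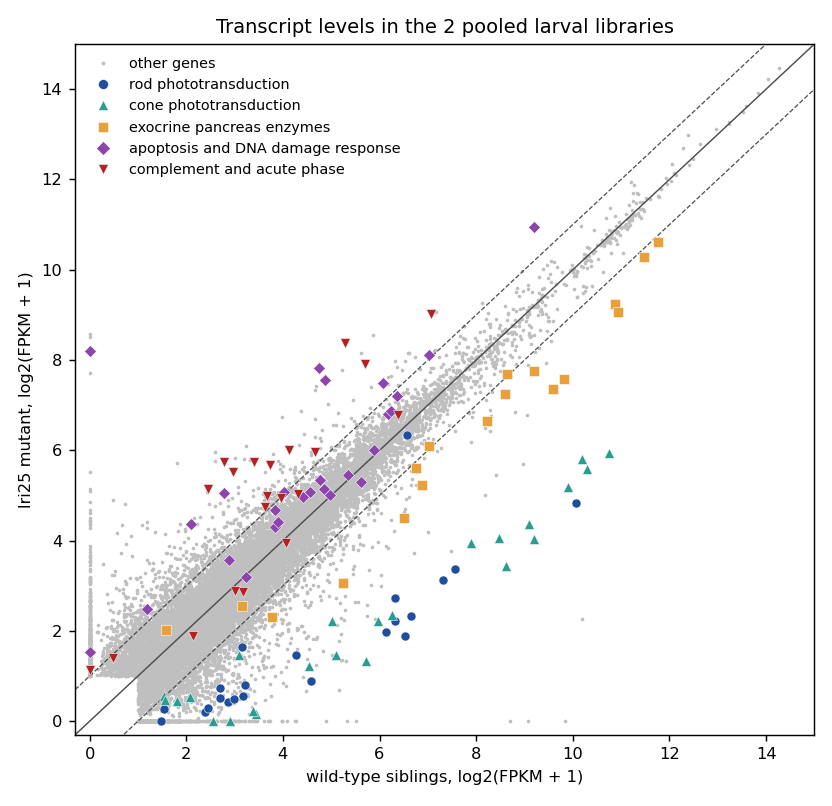
Each point is 1 of 20256 genes, with log2(FPKM + 1) in the wild-type siblings on the horizontal axis and in the lri25 mutant on the vertical axis. The solid line marks equal levels and the dashed lines a 2-fold difference. Of the cone genes, 23 of 24 lie under the lower dashed line, and complement and apoptosis genes lie mostly above the solid line.

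The cone list had the lowest median of all 63, at -3.68 (percentile 0, 24 genes, quartiles -4.49 and -2.75). Its members carry the light response of cones, from the opsins through the transducin and phosphodiesterase subunits. The ultraviolet opsin opn1sw1 (ENSDARG00000045677, chromosome 4, 12642189 to 12644872) was at 1707 FPKM in the wild type and 60.2 FPKM in the mutant. The green opsin opn1mw1 (chromosome 6, 41112733 to 41120324, a locus shared with opn1mw2) was at 960 and 35.2 FPKM, and the blue opsin opn1sw2 at 546 and 19.8 FPKM. Cone transducin alpha, gnat2 (ENSDARG00000042529, chromosome 8, 26078533 to 26144559, a locus shared with ampd2), was 39.5-fold lower, from 392 to 9.92 FPKM. The cone transducin gamma gene gngt2b, also at a shared locus, was at 1246 and 47.4 FPKM, and the cone phosphodiesterase inhibitory subunit pde6h, whose locus is shared with rbfox2, at 588 and 15.4 FPKM. The single member short of 2-fold on the log2(FPKM + 1) scale was opn1lw1, a red opsin at 1.91 and 0.481 FPKM, named after its values were seen.

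Rod genes were lower as well, with a list median of -2.55 (percentile 0, 22 genes, quartiles -4.15 and -2.17) that was -3.85 with a pseudocount of 0.1 and -1.23 with a pseudocount of 5. The rod photopigment rho (ENSDARG00000002193, chromosome 8, 55706882 to 55708436) was 38.6-fold lower in the mutant library. The outer segment disc protein prph2b was at 91.2 FPKM in the wild type and 2.72 FPKM in the mutant, and the recoverins rcvrna and rcv1, calcium sensors of photoreceptors, were 24.7-fold and 20.0-fold lower. Only gnb1a, a G protein beta subunit named here after its values were seen, was short of 2-fold in this list, at 94.1 and 80.4 FPKM. Genes of the retinoid cycle and the retinal pigment epithelium had a median of -0.67 (percentile 0), with 7 of 18 at least 2-fold lower. Among them irbp, the retinoid carrier of the space around photoreceptors, was at 128 and 17.4 FPKM, rdh8b at 7.07 and 0.479 FPKM, the retinol acyltransferase LRAT at 37.8 and 7.89 FPKM, and rlbp1a at 26.7 and 5.39 FPKM. Lens genes lay lower too, by less than rod and cone genes, with a median of -0.69 (percentile 0) and 6 of 30 members at least 2-fold lower. The lens water channels mipb and mipa were 4.22-fold and 3.29-fold lower, the gamma crystallin crygmx 3.30-fold and the lens membrane protein lim2.4 2.73-fold. Melanin pigment genes showed no such difference, with a median of 0.01 (percentile 55.0), tyrp1b at 145 and 147 FPKM and pmela, at a shared locus, 1.05-fold higher.

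**Figure D2:**
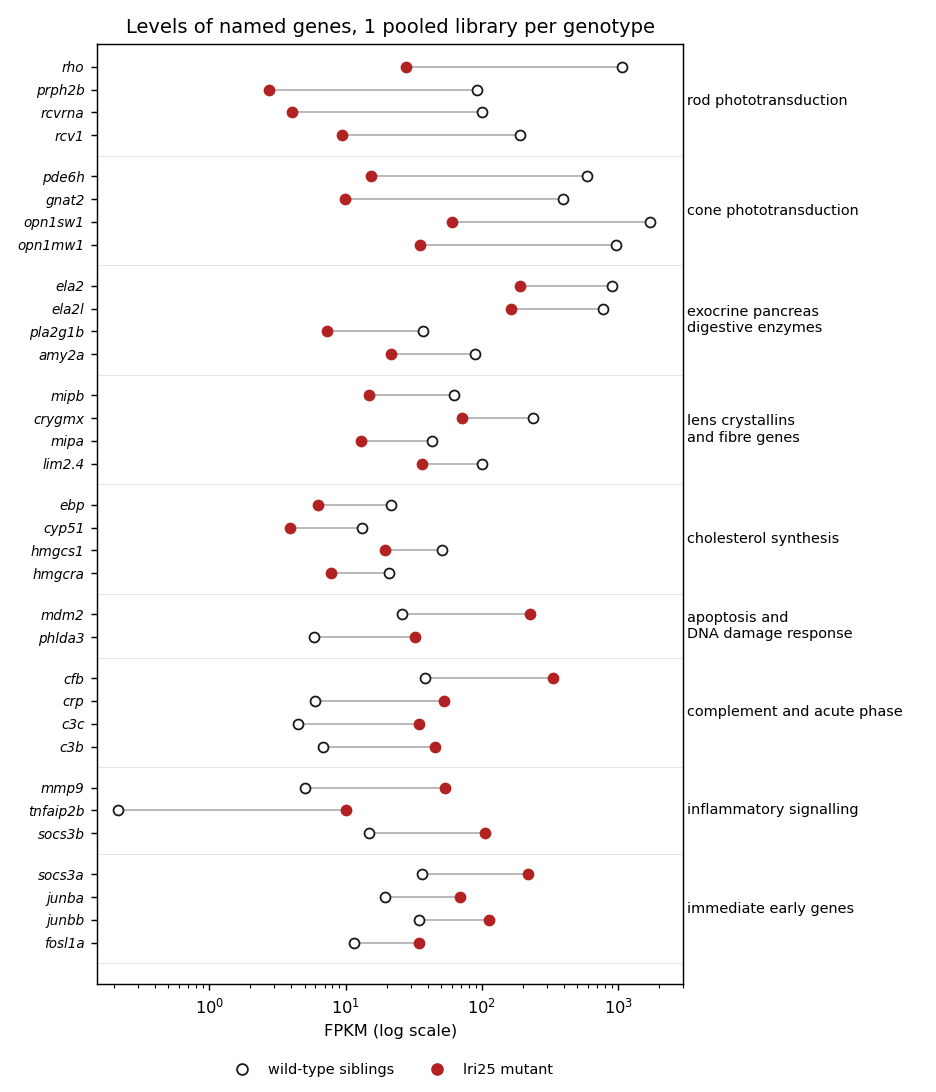
FPKM on a log axis for named genes of 9 lists, with open circles for the wild-type siblings and filled circles for the lri25 mutant, 1 pooled library each. Genes listed at 0 in 1 library are left out, and the widest gaps among the lower genes are those of rho, prph2b, pde6h and gnat2.

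Other sensory and nervous tissue lists were lower in the mutant by smaller amounts than the rod and cone lists. The chemosensory list had a median of -0.77 (percentile 0.01), with 4 of 10 genes at least 2-fold lower, among them the olfactory marker gene ompa at 12 and 1.69 FPKM and the G protein gamma subunit gng13b at 37.6 and 15.2 FPKM. Hair cell and lateral line genes had a median of -0.56 (percentile 0.48), or -0.24 with a pseudocount of 5, led by the calcium-binding genes s100t, at 97.3 and 30.3 FPKM, and s100s, at 34.5 and 17.1 FPKM. Synaptic genes had a median of -0.48 (percentile 0), with 21 of 23 members below 0 and 3 at least 2-fold lower. The vesicle fusion genes stxbp1b and snap25b were 5.81-fold and 2.41-fold lower, and grin1b, which encodes an NMDA receptor subunit, 2.29-fold. In the glia and myelin list, with a median of -0.61 (percentile 0), the myelin genes cldnk and mag were 2.89-fold and 2.64-fold lower. Of its 16 genes 3 were at least 2-fold lower and 1 at least 2-fold higher, s100b at 18 and 48.8 FPKM, named after its values were seen, and the mean of -0.39 lay inside the random range. Neural progenitor genes lay inside that range, at -0.22 (percentile 7.14), with her6 at 31.5 and 33.2 FPKM and her9 at 26.8 and 36.8 FPKM. Circadian clock genes had a median of -0.48 (percentile 0), or -0.31 with a pseudocount of 5, with 33 of 38 below 0, including rorca at 17.4 and 6.48 FPKM, npas2 at 6.91 and 2.31 FPKM and dbpa at 28.0 and 13.9 FPKM.

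Digestive enzymes made in the acinar cells of the pancreas had a median of -1.46 (percentile 0, 18 genes, quartiles -1.81 and -1.15). The elastases ela2 (ENSDARG00000056744, chromosome 8, 21914308 to 21919752) and ela2l, neighbours on that chromosome, the second at a locus shared with alas2, were at 900 and 769 FPKM in the wild type and at 190 and 164 FPKM in the mutant. Pancreatic phospholipase pla2g1b was 5.03-fold lower and the amylase amy2a 4.15-fold. Endocrine pancreas genes lay inside the random range, with a median of -0.24 (percentile 6.54), insulin (ins) at 102 and 68.1 FPKM and the glucagon gene gcga at 24.5 and 49.8 FPKM. Intestinal enterocyte genes were lower, with a median of -0.45 (percentile 0.05) and 15 of 18 below 0. Among these the fatty acid binding protein fabp2 was at 591 and 288 FPKM and the brush border protein vil1 at 96.5 and 50.4 FPKM. Cartilage and bone genes had a median of -0.51 (percentile 0), with 3 of 27 at least 2-fold lower and 6 above 0. In that list ucmaa and ucmab, which encode cartilage matrix-associated proteins, were 5.16-fold and 2.16-fold lower and matn3a was at 58.0 and 32.5 FPKM.

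The list of apoptosis and DNA damage response genes had a median of 0.67 (percentile 100) and a mean of 1.22, with 11 of 27 genes at least 2-fold higher and 0 at least 2-fold lower. The ubiquitin ligase gene mdm2 (ENSDARG00000033443, chromosome 4, 22061379 to 22071816), was at 25.9 FPKM in the wild type and 224 FPKM in the mutant. The gene phlda3 was 5.45-fold higher, and the pro-apoptotic gene pmaip1, at a locus of few bases, was listed at 0 in the wild type and at 291 FPKM in the mutant. DNA replication and cell cycle genes lay inside the random range at 0.08 (percentile 84.3), with 0 of 45 at least 2-fold apart and pcna at 142 and 176 FPKM.

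Complement and acute phase genes, which are expressed mainly in the liver, had the highest median of all lists, at 1.3 (percentile 100, quartiles 0.72 and 2.21), with 13 of 21 at least 2-fold higher. Complement factor B, cfb (ENSDARG00000055278, chromosome 21, 26810678 to 26825791), was at 38.1 and 331 FPKM. C-reactive protein (crp) was 8.88-fold higher, and the C3 genes c3c and c3b were 7.66-fold and 6.57-fold higher. The list of hepatocyte secreted and carrier proteins had a median of 0.53 (percentile 100), with 7 of 28 at least 2-fold higher and 0 at least 2-fold lower. Its members with the largest differences were the copper-binding ferroxidase ceruloplasmin (cp), at 24.4 and 160 FPKM, the iron hormone gene hamp2, at 9.59 and 52.4 FPKM, and the fibrinogen chains fgg and fga, 2.99-fold and 2.81-fold higher. The iron and heme list, which shares cp and hamp2 with it, had a median of 0.23 (percentile 98.7) that was 0.14 with a floor of 5 FPKM and -0.05 without genes at a shared locus, both inside the random range. In that list hmox1a was at 40.3 and 69.8 FPKM and the ferritin-like zgc:109934 was 2.11-fold higher.

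Inflammatory signalling genes had a median of 1.09 (percentile 100), with 14 of 23 at least 2-fold higher and 2 at least 2-fold lower. The matrix metalloproteinase mmp9 (ENSDARG00000042816, chromosome 8, 25134455 to 25148890) was 10.5-fold higher, from 5.07 to 53.1 FPKM. The cytokine signalling inhibitor socs3b was at 14.8 and 106 FPKM, tnfaip2b at 0.214 and 10.1 FPKM, and the chemokine-like si:ch211-122l24.4 was listed at 0 in the wild type and at 8.07 FPKM in the mutant. Immediate early genes had a median of 0.37 (percentile 99.98), or 0.60 with a floor of 5 FPKM, with 8 of 30 at least 2-fold higher. Among them were socs3a at 36.2 and 219 FPKM and the AP-1 subunits junba, junbb and fosl1a, 3.57-fold, 3.29-fold and 3.02-fold higher. Of these, socs3a, junba and junbb are also in the inflammatory list. The interferon list had a median of 0.83 (percentile 99.99), with 7 of 16 at least 2-fold higher, and was 1.59 with a pseudocount of 0.1, 0.38 with a pseudocount of 5 and 0.47 with no floor. The ubiquitin-like isg15 was listed at 0 in the wild type and at 19.3 FPKM in the mutant, b2m, the light chain of class I histocompatibility molecules, was at 2.99 and 12.7 FPKM, and irf1b at 1.75 and 6.60 FPKM. Neutrophil and mast cell genes had a median of 0.49 (percentile 99.94), with 5 of 15 at least 2-fold higher, and the myeloperoxidase mpx was at 2.93 and 7.21 FPKM. The 1 member at least 2-fold lower was the lysozyme gene lyz, at 60.9 and 27.4 FPKM, named after its values were seen. Among the higher members of the neutrophil list, mmp9 and mmp13a are also in the inflammatory list and lect2l is in the complement list. Macrophage genes had a median of 0.36 (percentile 99.3), with 5 of 20 at least 2-fold higher, and ctssb.1, a cathepsin, was at 3.86 and 21.9 FPKM. The macrophage median was 0.21 with a pseudocount of 5, and without genes listed at 0 it was 0.25 and inside the random range.

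Lipid genes lay on both sides. Cholesterol synthesis had a median of -0.60 (percentile 0), or -0.26 with a pseudocount of 5, with 8 of 25 genes at least 2-fold lower and 0 higher. The sterol enzymes ebp and cyp51 were 3.45-fold and 3.39-fold lower, hmgcs1 stood at 51.0 and 19.4 FPKM, and hmgcra, which encodes the rate-limiting reductase, at 20.7 and 7.75 FPKM. Fatty acid synthesis and storage had a median of -0.24 (percentile 2.06), with dgat1a at 13.4 and 7.41 FPKM and elovl6 at 24.1 and 14.8 FPKM. That list lay inside the random range without genes listed at 0 (percentile 2.54), against random lists not matched on level (percentile 3.65) and as a mean of -0.21 (percentile 7.73). Lipoprotein and lipid transport genes had a median of 0.30 (percentile 99.89), with 4 of 26 at least 2-fold higher. The apolipoprotein E gene apoeb was at 494 and 1005 FPKM, abca1a, a cholesterol exporter, at 7.41 and 19.6 FPKM, and apoba at 8.52 and 18.6 FPKM. Both apoeb and apoba are also in the hepatocyte list, and apoeb is in the macrophage list. The yolk list, of 8 genes with 5 above 0, had a median of 0.47 (percentile 99.1). Its cathepsins ctsla, at 708 and 1100 FPKM, and ctsd, at 166 and 276 FPKM, are also in the lysosome and autophagy list. With no floor the yolk median was 0.16, inside the random range. Fatty acid oxidation genes lay inside at -0.04, with ucp2 at 427 and 381 FPKM.

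Lists of protein turnover and secretion had higher medians by small amounts. All 36 proteasome genes measured lay above 0, with a median of 0.44 (percentile 100, quartiles 0.36 and 0.54), and 1 of them, the immune activator subunit psme2, passed 2-fold at 4.62 and 13.0 FPKM. The core subunits psmb1 and psma4 were at 89.1 and 67.1 FPKM in the wild type and at 150 and 107 FPKM in the mutant. All 32 vesicle coat and trafficking genes lay above 0 as well, with a median of 0.22 (percentile 98.8), and the coat subunit copa was at 46.3 and 63.4 FPKM. Lysosome and autophagy genes had a median of 0.35 (percentile 100), with 4 of 38 at least 2-fold higher and 1 lower, including ctsk at 14.0 and 53 FPKM and ctsc at 7.62 and 19.4 FPKM. The unfolded protein response list had a median of 0.34 (percentile 100), with 27 of 32 above 0, pdia4, a disulfide isomerase, 2.56-fold higher and dnajb9b 2.30-fold. Glucocorticoid axis genes had a median of 0.25 (percentile 98.6), with the cortisol-inactivating hsd11b2 at 45.2 and 84.4 FPKM and sgk1 at 159 and 239 FPKM, and the mean of 0.17 lay inside the random range. Slow muscle and cardiac genes had a median of 0.23 (percentile 98.5), with the natriuretic peptide gene nppa at 12.3 and 34.3 FPKM and the slow myosin smyhc1 at 93.8 and 162 FPKM, and lay at the edge of the range and not past it against random lists not matched on level.

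Housekeeping and bulk tissue lists lay inside the random range. Cytosolic ribosomal proteins had a median of -0.07 and nuclear oxidative phosphorylation genes also -0.07, with 0 of 71 and 0 of 51 genes at least 2-fold apart, rps2 at 3942 and 3792 FPKM and cox4i1 at 684 and 591 FPKM. Mitochondrially encoded genes had a median of 0.06, with mt-co2 at 14635 and 15431 FPKM. Fast skeletal muscle had a median of 0.07, with pvalb2 at 19709 and 22757 FPKM, and skin keratinocytes 0.12, with the keratin krt4 at 4981 and 6639 FPKM. Heat shock genes had a median of 0.17, the amino acid response 0.16, oxidative stress genes 0.06 and glycolysis -0.11, with hspa8 at 2196 and 2422 FPKM, chac1 at 634 and 712 FPKM, gstp1 at 533 and 554 FPKM and gapdh at 2557 and 3339 FPKM. Ribosome biogenesis (0.04), spliceosome (0.01) and tRNA synthetase genes (0.21) were inside the range too.

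**Figure D3:**
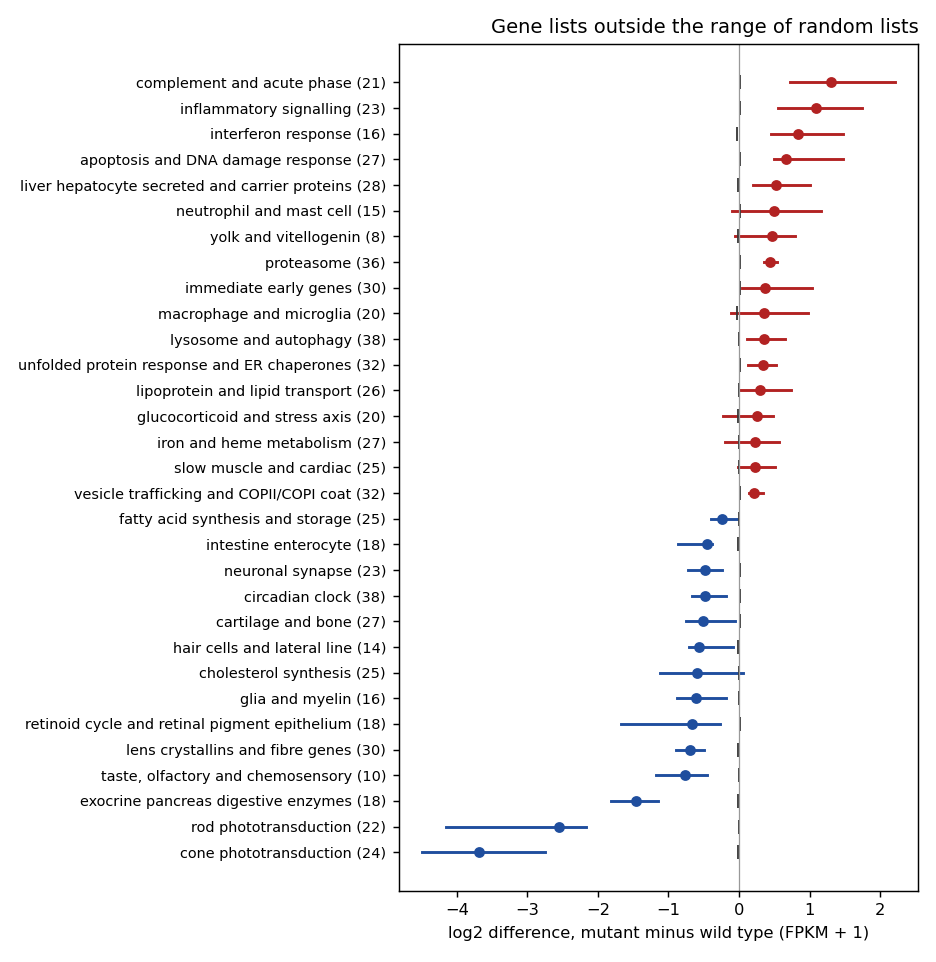
Median log2 difference, mutant minus wild type, of the 31 lists outside the random range (dots), with the quartiles of their members (bars) and the median of matched random lists (ticks), and the number of genes measured in brackets. The 14 lists below run from cone phototransduction at -3.68 to fatty acid synthesis at -0.24, and the 17 above from vesicle trafficking at 0.22 to complement at 1.3.

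The genes farthest apart included several small nucleolar RNA genes inside other genes, which guide the modification of ribosomal and other RNAs. SNORA47, SNORA16 and SNORA68 were listed at 918, 537 and 418 FPKM in the wild type and at 0 in the mutant, and SNORA27 and SNORA79 were listed at 0 in the wild type and at 378 and 209 FPKM in the mutant. All 5 shared their locus with other genes. The Eph receptor gene epha4b (chromosome 2, 40081899 to 40266727) was at 1166 and 3.80 FPKM, for which the authors' deposited table gave p = 0.116. Among genes listed at 0 in the wild type, the chemokine cxcl-c1c was at 24.6 FPKM in the mutant, KYNU (2 of 2) at 23.4, pcp4b at 20.5, the leptin gene lepb at 20.4, clasp1b at 13.1 and MYO18B (3 of 4) at 11.8 FPKM. An entry for cpn1 was listed at 0 and 18.4 FPKM, at a locus it shared with other entries of that name. The helicase gene dhx57 was at 2.5 and 51.5 FPKM. Of these small nucleolar RNA genes and the genes named after them, only cxcl-c1c and lepb were called different in the authors' deposited table.

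In the authors' deposited table, 68 genes were called different between these libraries at q = 0.05 or less, 29 higher and 39 lower in the mutant, out of 14613 genes tested. Of the 39 lower calls in the authors' deposited table, 15 belonged to the 4 eye lists, among them rho, gnat2, opn1sw1, opn1mw1 and irbp, each with q = 0.0133, the smallest in the table. Further lower calls, such as pdcb, prom1b and rs1a, belonged to the photoreceptor list written after the results had been seen. Among the higher calls in the authors' deposited table, mdm2, cfb, c3b, c3c, mmp9, socs3a, socs3b, cp, isg15 and lepb had that same q. The elastases ela2 and ela2l and the lens channel mipb were called lower in the authors' deposited table at p = 0.0002. By contrast, pmaip1 had p = 0.0371 in the authors' deposited table and was not called. The genes crp, tnfaip2b and phlda3 were not called either. Of the 68 calls in the authors' deposited table, 18 were genes listed at 0 in 1 library, 8 in the wild type and 10 in the mutant. A test on 2 libraries compares those libraries and not the genotypes.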

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

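Alternatives that left out genes listed at 0 or genes at a shared locus were chosen after seeing the data, and the others before. The counts of genes at least 2-fold apart went from 1232 higher and 1442 lower to 1866 and 2219 with a pseudocount of 0.1, 296 and 361 with a pseudocount of 5, 612 and 721 with a floor of 5 FPKM, 394 and 509 at a 3-fold threshold, and 797 higher without genes listed at 0. Fewer genes qualify by construction under the last 3. The authors' 68 calls come to 0 higher and 0 lower at a q of 0.01 by construction, since the smallest q in their table was 0.0133, so that alternative tests nothing. Of the lists outside the random range, iron and heme turned to -0.054 without genes at a shared locus, and its median was 0.14 with a floor of 5 FPKM or with members at 5 FPKM only, and its mean 0.26, all inside the range. Yolk was inside at 0.16 with no floor and without genes at a shared locus, and at 0.42 as a mean. Macrophage genes were inside at 0.25 without genes listed at 0 and at 0.29 without genes at a shared locus. Fatty acid synthesis was inside at -0.24 without genes listed at 0 and against random lists not matched on level, and at -0.21 as a mean. The glucocorticoid list was inside at 0.24 without genes at a shared locus, 0.25 against unmatched lists and 0.17 as a mean, slow muscle and cardiac at 0.23 against unmatched lists, and glia and myelin at -0.39 as a mean. The cause was not tested. The other 24 of the 31 lists outside kept their side under every alternative that gave a value, though their size depended on how low values were treated. With a pseudocount of 5 the medians of 6 lists were over 1.5 times smaller, namely rod genes at -1.23, interferon at 0.38, cholesterol synthesis at -0.26, hair cells at -0.24, macrophage genes at 0.21 and the circadian clock at -0.31. With a pseudocount of 0.1, 2 lists were over 1.5 times larger, rod genes at -3.85 and interferon at 1.59. Of the 32 lists inside, 27 did so, and ionocytes, erythroid, lymphoid and heat shock genes passed the range with a pseudocount of 5, lymphoid genes also with no floor, and fibrillar collagen and matrix as a mean. Of the 197 named genes, 191 stayed on their side of 2-fold with a pseudocount of 0.1 and 6 newly passed it. With a pseudocount of 5, 179 stayed and 18 fell short of it. Rescaling moved 1 gene short and 1 past 2-fold, and centring moved 2 short. Floors and leaving genes out do not change the value of a gene, so those alternatives test nothing for single genes. The trimmed-mean factor of the mutant over the wild type was -0.02 on the log2 scale and centring subtracted a median of 0.025, and both move a list and its random lists almost alike, so neither tests on which side a list lies. Depth limits genes near 1 FPKM, which rest on few fragments. No paired analysis was possible because each group has 1 library with no shared number.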

Other observations

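The tests on the lens, bipolar cells, delay, scaling, leukocytes, liver, the pancreas, the gut and the chromosome windows were chosen only after the results they weigh had been seen. The lists not yet described lay inside the random range. Iridophore and purine synthesis genes had a median of 0.11, erythroid genes 0.19, vascular endothelium 0.13, swim bladder and notochord 0.13, fibrillar collagen and matrix 0.14, one-carbon and nucleotide synthesis 0.13 and cilia 0.10. On the other side of 0 were ionocytes at -0.20, lymphoid genes at -0.46 over 5 genes, hypoxia at -0.14, bile acid targets at -0.14, xenobiotic metabolism at -0.12, amino acid catabolism at -0.01, thyroid and pituitary at -0.09 and kidney at -0.18. Single members stood apart inside several of these. In the cilia list tmem237a, which encodes a protein of the ciliary transition zone, was at 24.7 and 2.51 FPKM against a list median near 0. In the hypoxia list igfbp1a, an inhibitor of insulin-like growth factors, was at 96.7 and 284 FPKM, while ldha differed little, at 201 and 172 FPKM. The smooth muscle actin acta2 was 2.32-fold lower. The endothelial tight junction gene cldn5b was 2.39-fold higher, at a locus shared with 3 other genes, and p was 0.581 in the authors' deposited table. In the slow muscle and cardiac list, which lay above the random range, the natriuretic peptide gene nppb (BX323876.2 in the table) also stood apart. It was listed at 0 in the wild type and at 33.0 FPKM in the mutant.

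Several more genes, chosen after their values were seen, stood apart. In the matrix list timp2b was at 8.43 and 67.0 FPKM and fn1b at 42.8 and 138 FPKM, both at a shared locus, and mmp2 was at 78.3 and 250 FPKM. In the oxidative stress list the thioredoxin txn was at 47.7 and 284 FPKM. The cyclin gene ccng1 and the cell cycle inhibitor cdkn1a were at 589 and 66.3 FPKM in the wild type and at 1970 and 179 FPKM in the mutant. Inner retinal neuron genes had a median of -1.0 (percentile 0), with 12 of 24 at least 2-fold lower, 0 at least 2-fold higher and vsx1, a bipolar cell factor, at -2.82, and photoreceptor genes outside phototransduction had a median of -1.96, with 28 of 40 at least 2-fold lower. Leukocyte identity genes, 11 of them also in a list fixed earlier, had a median of 0.39 above the random range (percentile 99.93), with 4 of 29 at least 2-fold higher and 1, the lysozyme gene lyz, lower at 60.9 and 27.4 FPKM. Along the chromosomes 12743 genes were placed, a smaller set than the 20256 compared, and 1333 of them (10.5%) were at least 2-fold apart. Their fullest window of 30 genes held 12 such genes, on chromosome 23 from 38345651 to 42954118. The fullest window in 1000 shuffles held a median of 10 and a maximum of 15, and 7.1% of shuffles were as full.

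Photoreceptor lists had the lowest medians of the 63 lists, though single genes elsewhere lay farther apart. A smaller share of all eye tissue as the whole cause is argued against by lens genes, whose lower quartile of -0.90 lay well above the rod and cone medians of -2.55 and -3.68, though it stays open as a part. A scaling factor of the library as the whole cause would lower all lists alike, and is argued against by ribosomal protein genes, with a lower quartile of -0.12. A broad loss of photoreceptor transcripts or fewer photoreceptor cells may underlie the pattern, since 30 photoreceptor genes outside phototransduction whose values had not been seen had a median of -1.78, with 18 at least 2-fold lower. A whole-larva library does not separate these from a smaller retina or a delay of the larvae. Bipolar cell genes had a median of -1.91, but were picked from the inner retinal list after its values were seen, so they decide nothing. The whole inner retinal list, tested earlier, had a median of -1 and a lower quartile of -1.27. It fell less than the rod and cone lists, but also holds genes used outside the eye, so a smaller retina stays open. A delay was expected to put the neural progenitor and cell cycle lists above the random range, and both lay inside it. The progenitor median of -0.22 lay below 0, the sign written as counting against a delay, but its quartiles lay on both sides of 0. Several other tissue lists were lower, such as glia and myelin at -0.61, cartilage and bone at -0.51 and enterocytes at -0.45. Fast muscle at 0.07 and skin at 0.12 were not. These lists were not weighed against a delay, which stays open.

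Complement and inflammatory transcripts were higher together. More leukocytes in the mutant pool as the whole cause was weighed with leukocyte identity genes. On the scale used here, their upper quartile of 0.62 lay under the inflammatory median of 1.09. Several of these leukocyte genes lie near 1 FPKM, where the pseudocount shrinks differences. On plain ratios hck, ncf4, parvg and lyn were 2.07-fold, 2.28-fold, 2.3-fold and 2.33-fold higher, while csf1ra and itgb2 differed little and lyz was lower. The inflammatory median changed little, to 1.15 with a pseudocount of 0.1. The gap depends on the scale and does not decide, so more leukocytes stay open. A larger share of liver as the whole cause of the complement difference is argued against by the other 27 hepatocyte genes, with a median of 0.50 and an upper quartile of 0.92 under the complement median of 1.3. The leukocyte list itself lay above the random range, and shifts in leukocytes and smaller shifts in liver could add to the pattern. An acute phase response in the mutants remains a hypothesis that these pools alone do not test.

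Digestive enzymes fell further below the wild type than endocrine pancreas and enterocyte genes, with medians of -1.46, -0.24 and -0.45. A loss of exocrine and endocrine pancreas alike as the whole cause is argued against by endocrine genes, whose lower quartile of -0.57 lay above the exocrine median of -1.46. Endocrine genes do not weigh a smaller exocrine part of the pancreas, which stays open. Less digestive tract tissue as the whole cause is argued against by enterocyte genes, which were lower too, at a median of -0.45, but with a lower quartile of -0.86 above the exocrine median, and it stays open as a part. Fewer acinar cells or lower enzyme expression per cell both stay open and may act together.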
